A study of Mus musculus with 9 samples.

How the data were processed

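The series holds 9 RNA sequencing libraries of mouse lung adenocarcinoma cells, 3 biological replicates each at days 0, 4 and 21, and all 9 were used. Polyadenylated RNA was isolated with RNeasy columns, treated with TURBO DNase and sequenced by a standard Illumina protocol, per the labels. The deposited table gives FPKM values that the authors made with TopHat2 2.0.5 and Cufflinks 2.0.2 on the mm9 mouse genome, per the submitters' processing notes. The annotation, the parameters and any scaling between libraries are not stated. The table has 1 line per gene symbol, with 23235 symbols, no symbol repeated, and 9 value columns, none of which was left unused. Of the symbols 20846 (89.7%) match the current mouse gene names at hand, which follow a later build than mm9, so no positions are given and genes are named by their symbols alone.

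Sums of FPKM per library were 650209, 627556 and 661774 at day 0 (replicates A, G and M), 391062, 499599 and 555471 at day 4 and 641462, 614048 and 655659 at day 21. Fragment numbers are not in the table, so no counting interval can be given. Depth relative to day 0 replicate A could only be estimated, from the spacing of the lowest FPKM values, at 0.461 to 1.26. Small RNA genes (names in Snord, Snora, Scarna and Mir) held 10.0% to 28.1% of the FPKM sum of a library.

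A pseudocount of 1 was added to FPKM and values were taken to the log2 scale. Genes with at least 1 FPKM in at least 3 libraries were tested, 11168 in all, of which 81 are small RNA genes. Each comparison was tested with limma 3.58.1 in R 4.3.3 in a fit of all 9 libraries with day as the only factor and an intensity trend (moderated test, two-sided, prior degrees of freedom 2.97), and p was adjusted by the Benjamini-Hochberg method over the genes of that comparison with a threshold of 0.05. Kras, the target of the hairpin, was also read on its own, adjusted over 1 gene, which leaves p as it is. The 3 comparisons were day 4 with day 0, day 21 with day 0 and day 21 with day 4. An exact permutation test of 3 against 3 cannot give p under 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

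A set of 25 gene lists was fixed before the data were examined, as were the tests, the threshold and most alternatives. The lists cover ERK output, RAS pathway genes, epithelial and mesenchymal genes, YAP/TAZ targets, Hippo components, AP-1 factors, DNA replication, mitosis, CDK inhibitors, p53 targets, alveolar and airway genes, gastrointestinal genes, glycolysis, oxidative phosphorylation, lysosome and autophagy, sterol synthesis, interferon response, receptor tyrosine kinases, NRF2 targets, stress and amino acid response, ribosomal proteins, and markers of fibroblasts, immune cells and endothelium. ERK output, epithelial, mesenchymal and YAP/TAZ lists were central because the title of the series names KRAS, YAP1 and the epithelial to mesenchymal transition. The 22 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists of a comparison. Camera was also run with an estimated correlation between genes, under which 0 lists passed in any comparison, with 2, 1 and 0 lists at an unadjusted p under 0.05. Fry, which tests whether the genes of a list move on balance, passed 0 lists after adjustment and 3, 0 and 0 at an unadjusted p under 0.05. A list value is the mean log2 difference of its tested members less the median of all tested genes. The plan named the mean alone, and the median was taken off after the data showed a shift of all genes in 1 library, day 4 replicate A, whose median deviation from day 0 was −0.50, against −0.10 and 0.02 in day 4 replicates G and M. A list score of a library is the mean of the same members' log2 values, less the day 0 mean of each and less the shift of the median gene. The count of members past limma is given over all genes and adjusted over the list alone.

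Genes were named by a rule. Kras, Yap1, Fos, Cdh1 and Vim were always named. Named for each comparison were the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, without overlap between the groups and with a mean of at least 5 FPKM in a group. For each list the rule took up to 4 members with the largest change among those past the threshold over all genes, or the 2 members with the highest FPKM where none passed. Members named because they passed over the list alone, other members that serve as examples (such as Cyr61, Amotl2, Ankrd1, Fn1, Sparc and Cdh2), Mki67, Nkx2-1, Hnf4a, Sdc3 and Gm5779 were chosen after their values were seen.

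Alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalisation, the libraries of 2 groups alone, the replicate letter as a block with and without scaling, a robust fit, camera with an estimated correlation, and leaving out each library and each letter. Added after the data were seen were fits without small RNA genes, with and without scaling, weights per library, and days 4 and 21 as 1 group. Keeping several lines per symbol was planned and had nothing to act on. The pipeline was tested on simulated data with the spread of these libraries in which 200 of 11168 genes were changed. It recovered 17.9%, 76.1% and 98.5% of genes changed 2-fold, 4-fold and 16-fold between day 4 and day 0, and made 9 false calls among 10968 unchanged genes. Of 1000 random gene lists, 1.4% to 2.4% reached an unadjusted camera p under 0.05. The simulated genes varied independently of each other, while the fixed lists had a median estimated correlation of 0.42 (highest 0.96). The random lists therefore do not test how camera at the preset correlation behaves with correlated genes.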

Results

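Polyadenylated RNA was sequenced from primary lung adenocarcinoma cells of mice of the 129/SvJae strain. The tumours came from the KP model, which combines a conditional activated Kras allele with a floxed p53 gene. The cells, called KP-KrasA, hold a doxycycline-inducible short hairpin RNA against Kras, placed in the 3' untranslated region of a GFP gene. The 9 libraries fall into 3 groups of 3 biological replicates, taken at day 0, day 4 and day 21, and the replicates carry the letters A, G and M. The doxycycline schedule is not stated. No group without the Kras hairpin is among the 9 libraries. A difference from day 0 therefore cannot be told apart from an effect of doxycycline or of time. The deposited FPKM values (fragments scaled by transcript length and by mapped fragments) summed to between 391062 and 661774 per library, lowest in day 4 replicate A. The table gives no fragment counts, so the number of fragments behind each value is unknown, and between 10575 and 10896 genes per library reached 1 FPKM. Values below are means with the standard deviation over 3 replicates, and all 11168 genes that passed the filter were tested in each comparison.

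The first question was whether the hairpin lowered its target, Kras, the small GTPase at the head of the RAF, MEK and ERK kinase cascade. Kras averaged 15.3 ± 9.13 FPKM (n = 3) at day 0, 2.59 ± 0.64 at day 4 and 2.48 ± 0.49 at day 21. The day 0 libraries measured 25.6, 7.98 and 12.5 FPKM, and the 6 later libraries lay between 1.93 and 3.32, so the groups did not overlap. The mean was 83.1% lower at day 4 and 83.8% lower at day 21 than at day 0. With days 4 and 21 as 1 group, Kras fell by 2.07 on the log2 scale (exact permutation p = 0.0119, two-sided, the smallest that the 84 splits of 6 against 3 allow), a grouping chosen after the values were seen. In the limma fit Kras fell by 2.05 from day 0 to day 4 and by 2.09 to day 21, with adjusted p = 0.000313 and 0.000273 when adjusted over Kras alone, the 1 gene fixed beforehand as the target. Adjusted over all genes, limma gave an adjusted p of 0.437 and 0.507, so Kras did not pass among all genes. The day 21 mean differed from that of day 4 by −0.04 on the log2 scale, with an adjusted p of 0.915 over Kras alone in the same limma fit. The paralogs of Kras and the kinases below it, a list of 20 genes, passed no test in any comparison. Relative to all genes they differed by 0.08 at day 4 (camera adjusted p = 0.959, its direction opposite to that of the mean) and by 0.08 at day 21 (adjusted p = 0.697). Mapk1, which encodes the kinase ERK2, measured 62.0 ± 1.71, 53 ± 16.4 and 64.9 ± 2.38 FPKM at days 0, 4 and 21, and Mapk3, which encodes ERK1, 116 ± 27.6, 89.9 ± 5.54 and 107 ± 55.9.

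**Figure D1:**
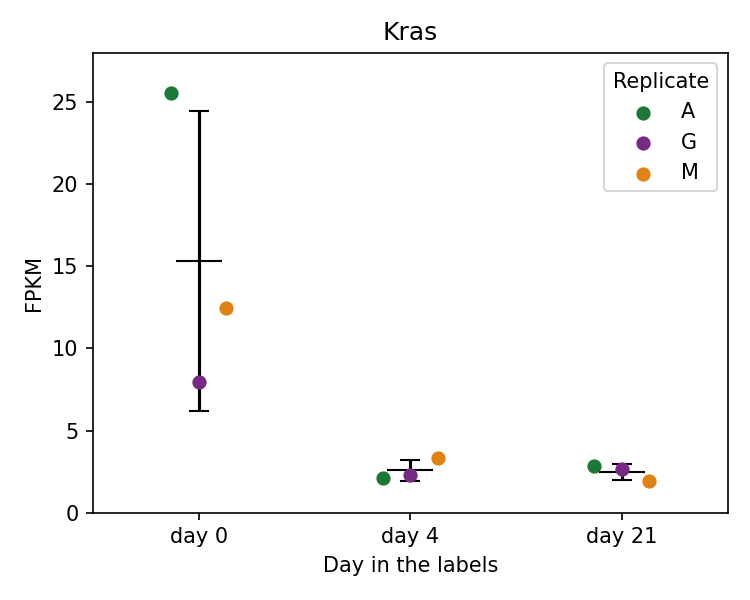
Kras FPKM in each of the 9 libraries by day, with the mean of 3 replicates and bars for 1 standard deviation. The 3 libraries of day 0 lie between 7.98 and 25.6 FPKM and the 6 later libraries between 1.93 and 3.32.

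The comparison of day 4 with day 0 asked which genes and pathways differed early in the series. Several genes that ERK signalling switches on were lower. Dusp6, which encodes a phosphatase that removes the activating phosphates of ERK, measured 59.3 ± 5.96 FPKM (n = 3) at day 0 and 23.1 ± 1.28 at day 4. Spry4, an inhibitor of receptor signalling to RAS, went from 4.08 ± 1.09 to 1.13 ± 0.42 FPKM, and the transcription factors Etv4 and Etv5 from 14.9 ± 7.07 to 3.59 ± 3.59 and from 14.3 ± 5.66 to 3.30 ± 1.49. Hmga2, a chromatin protein of embryonic tissues, went from 22.8 ± 2.95 to 10 ± 2.66 FPKM. These 5 of the 28 tested ERK output genes fell in limma when adjusted over the list alone, with adjusted p between 0.0119 and 0.0474, and 10 of the 28 were lower at an unadjusted p under 0.05. All 3 day 4 values lay below all 3 day 0 values in 9 of the 28 and above them in 1, where chance gives 2.8 over both directions. These counts take FPKM as deposited, and the median log2 difference of all genes was −0.21, which favours values below. In the same count 11 of 16 glycolysis, 13 of 31 oxidative phosphorylation and 29 of 52 ribosomal protein genes lay below. Of RAS pathway genes 0 of 20 did, and of epithelial genes 2 of 17. Over all genes 0 of the 28 passed. Emp1 and Ccnd1, the members with the highest FPKM, measured 620 ± 84 and 300 ± 54.0 FPKM at day 0 and 349 ± 178 and 186 ± 111 at day 4, and neither passed. As a list, ERK output fell by 0.31 on the log2 scale relative to the median of all genes (camera adjusted p = 0.0131, and adjusted p = 0.622 with an estimated correlation). The call ended without day 0 replicate G (−0.31, adjusted p = 0.0519) and without day 4 replicate A (−0.16, adjusted p = 0.13). It also ended with weights per library (−0.11, camera adjusted p = 0.475). Dusp6, Spry4 and Etv5 kept their call over the list alone after median-of-ratios scaling, and Etv4 and Hmga2 did not. The log2 differences of Etv4 and Hmga2 were −2.01 and −1.13, and −1.88 and −0.91 after that scaling. Of the 12 settings that left out a library or a letter, Spry4 and Etv5 kept it in 9, Dusp6 in 7, Hmga2 in 4 and Etv4 in 2.

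YAP and TAZ target genes, the transcripts raised by the co-activators that the Hippo pathway restrains, were higher at day 4. Ctgf and Cyr61, secreted matrix proteins, measured 72.7 ± 11.4 and 19.2 ± 14.2 FPKM (n = 3) at day 0 and 336 ± 416 and 201 ± 255 at day 4. The wide spread at day 4 came with replicate M, in which Ctgf was 816 and Cyr61 493 FPKM. Amotl2, an angiomotin family member, measured 18.9 ± 6.67 and 53.6 ± 28.4 FPKM. As a list, the 20 tested YAP/TAZ targets rose by 0.93 on the log2 scale relative to all genes (camera adjusted p = 8.5e-08, and adjusted p = 0.381 with an estimated correlation), and by 0.59 without day 4 replicate M. In only 1 of the 20 did all 3 day 4 values lie above all 3 day 0 values and in 0 below, where chance gives 2 over both directions, again in FPKM as deposited. No member passed limma over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05, all higher. Myof, the member with the highest FPKM, measured 224 ± 34.7 and 178 ± 25.6. Yap1 itself measured 27.2 ± 1.23 FPKM at day 0 and 26.9 ± 10.4 at day 4, a log2 difference of −0.09 that became 0.13 after median-of-ratios scaling and passed in neither. The 19 tested Hippo components rose by 0.42 (camera adjusted p = 0.00539, and adjusted p = 0.622 with an estimated correlation), with 0.28 and an adjusted p of 0.169 without day 4 replicate M. Among them, Jub, a LIM protein that binds the LATS kinases, measured 25.2 ± 8.92 and 56.2 ± 27.1 FPKM, and Wwc1, an upstream scaffold of the pathway, 73.1 ± 0.35 and 86.8 ± 33.2. AP-1 factors rose by 0.38 (camera adjusted p = 0.00464, and adjusted p = 0.458 with an estimated correlation), or 0.23 without day 4 replicate M. In that list of 9 tested genes, Jun rose from 8.20 ± 2.90 to 21.9 ± 8.63 FPKM (limma, adjusted over the list alone, adjusted p = 0.0282), a call kept after median-of-ratios scaling and in 5 of the 12 settings that left out a library or a letter. Jund and Junb measured 129 ± 20 and 60.1 ± 10.7 FPKM at day 0 and 115 ± 4.42 and 70.8 ± 33.2 at day 4, and Fos 1.22 ± 0.75 and 0.58 ± 0.48.

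Mesenchymal genes were higher and epithelial genes lower in mean at day 4, and only the former passed as a list. The 17 tested mesenchymal genes rose by 0.71 on the log2 scale relative to all genes (camera adjusted p = 0.000689, and adjusted p = 0.549 with an estimated correlation). The call ended with no expression filter (0.33, camera adjusted p = 0.0894). The 17 genes rose by 0.32 without day 4 replicate M. In that library Col1a1, a collagen chain also abundant in fibroblasts, reached 68.1 FPKM, and Sparc, a matrix glycoprotein, 593. The members did not move together: Cdh2, N-cadherin, measured 4.65 ± 0.78 FPKM (n = 3) at day 0 and 9.92 ± 5.37 at day 4, while S100a4, a calcium-binding protein, measured 3401 ± 1458 and 1080 ± 279 and Vim 1767 ± 70.0 and 1503 ± 458. No member passed limma over all genes or over the list alone, and 3 had an unadjusted p under 0.05, 1 higher and 2 lower. The log2 difference of Vim, −0.28, became 0.28 under quantile normalisation. The 17 tested epithelial genes differed by −0.36 relative to all genes (camera adjusted p = 0.267), a list that passed without day 4 replicate A (−0.72, adjusted p = 0.00405). The keratin genes Krt8 and Krt19 measured 3136 ± 347 and 1996 ± 631 FPKM at day 0 and 1989 ± 444 and 1560 ± 101 at day 4, and Cdh1, E-cadherin, 177 ± 53.6 and 136 ± 26.8. No epithelial member passed limma, and 2 had an unadjusted p under 0.05. Of the markers of other cell types, 1 of 12 fibroblast genes (Col1a1), 1 of 12 immune genes (Cd68, 1.76 ± 0.52 and 1.55 ± 0.77 FPKM) and 2 of 10 endothelial genes (Egfl7, 3.48 ± 0.17 and 2.61 ± 0.27, and Esam, 1.72 ± 0.88 and 0.65 ± 0.30) were expressed enough to be tested, and none passed.

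Glycolytic genes were lower at day 4. Slc2a1, which encodes the glucose transporter GLUT1, measured 46.4 ± 10.9 FPKM (n = 3) at day 0 and 26.5 ± 4.84 at day 4, Ldha, lactate dehydrogenase A, 1060 ± 109 and 511 ± 224, and Pkm2, pyruvate kinase, 1211 ± 200 and 713 ± 198. With Pfkl, Aldoa and Tpi1, these made up the 6 of 16 tested members that fell in limma when adjusted over the list alone, each with an adjusted p of 0.0434. None of the 16 passed over all genes, 8 had an unadjusted p under 0.05, and none of the 6 kept its call over the list alone after median-of-ratios scaling or without day 4 replicate A. As a list, glycolysis fell by 0.42 on the log2 scale relative to all genes (camera adjusted p = 0.00011, and adjusted p = 0.458 with an estimated correlation). Gapdh, its member with the highest FPKM, measured 2015 ± 598 and 1182 ± 598. The 16 tested NRF2 targets, which handle oxidants, fell by 0.51 (camera adjusted p = 0.00101, and adjusted p = 0.458 with an estimated correlation). Among them Slc7a11, the cystine transporter, fell from 14.8 ± 14.8 to 1.41 ± 0.92 FPKM and G6pdx, the first enzyme of the pentose phosphate pathway, from 49.8 ± 1.87 to 23.6 ± 7.69 (limma, adjusted over the list alone, adjusted p = 0.0350 for each). Both kept that call after median-of-ratios scaling and lost it without day 4 replicate A. Their log2 differences were −2.39 and −1.10 with all libraries, and −2.08 and −0.81 without that replicate. Gsta4 and Gstm1, glutathione transferases, measured 494 ± 91.4 and 352 ± 170 at day 0 and 405 ± 292 and 253 ± 253 at day 4. The 18 tested genes of sterol synthesis fell by 0.44 (camera adjusted p = 0.000689, and adjusted p = 0.615 with an estimated correlation), or by 0.28 without day 0 replicate A. Fdps, which makes farnesyl diphosphate, measured 224 ± 124 and 112 ± 24.6 FPKM, and Srebf2, the transcription factor that drives the pathway, 105 ± 25.4 and 71.8 ± 3.72. Oxidative phosphorylation fell by 0.16 (camera adjusted p = 0.000689, and adjusted p = 0.652 with an estimated correlation), with Atp5b at 755 ± 52.1 and 581 ± 150 FPKM and Ndufa4 at 490 ± 115 and 371 ± 107. Under quantile normalisation it stood at −0.0492 and the call ended. Ribosomal protein genes fell by 0.25 (camera adjusted p = 4.4e-12, and adjusted p = 0.458 with an estimated correlation), by 0.41 without day 4 replicate A and by 0.15 without day 4 replicate G, but stood at 0.03 under quantile normalisation. Rplp1 measured 2775 ± 356 and 2014 ± 179 FPKM and Rplp0 2153 ± 425 and 1468 ± 242. Of the members of the sterol, oxidative phosphorylation and ribosomal lists, 0 passed limma over all genes or over the list alone, and 4, 2 and 21 had an unadjusted p under 0.05.

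Cell cycle genes were lower in mean at day 4, with 1 library deciding the value. Mki67, a marker of proliferating cells, measured 5.87 FPKM in day 4 replicate A, 67.1 in G and 32.2 in M, against 47.3 to 69.6 at day 0. Mitosis genes fell by 0.79 on the log2 scale relative to all genes (camera adjusted p = 0.00148, and adjusted p = 0.661 with an estimated correlation), and stood at −0.04 without day 4 replicate A (adjusted p = 0.617) and at −1.29 without day 4 replicate G. DNA replication genes fell by 0.67 (camera adjusted p = 0.00595, and adjusted p = 0.683 with an estimated correlation), and stood at 0.07 without day 4 replicate A (adjusted p = 0.463), at −0.60 without day 0 replicate G (adjusted p = 0.0880), and at −1.08 and −1.02 without day 4 replicates G and M. Ube2c and Top2a, genes of mitosis, measured 160 ± 11.0 and 133 ± 16.6 FPKM (n = 3) at day 0 and 92.3 ± 67.3 and 86.1 ± 65.6 at day 4. Pcna and Rrm2, genes of DNA synthesis, measured 238 ± 19.3 and 90.9 ± 27.9 at day 0 and 154 ± 102 and 72.8 ± 64.7 at day 4. No member of either list passed limma, and 0 had an unadjusted p under 0.05. The genes of CDK inhibitors did not pass as a list (0.10, camera adjusted p = 0.959, with the direction of the camera test opposite to that of the mean), with Cdkn2a at 198 ± 31.9 and 215 ± 91.6 FPKM and Cdkn2b at 56.3 ± 19.7 and 63.4 ± 37.5. The 19 tested p53 targets rose by 0.28 (camera adjusted p = 0.0271, and adjusted p = 0.458 with an estimated correlation), although their median log2 difference before this correction was −0.04. That call ended without day 0 replicate G, day 0 replicate M or day 4 replicate A, at adjusted p of 0.117, 0.0629 and 0.101, and after median-of-ratios scaling (adjusted p = 0.0546). Bax and Phlda3, p53 targets that act in cell death, measured 125 ± 4.86 and 35.8 ± 17.1 FPKM at day 0 and 95.1 ± 37.3 and 55.1 ± 44.5 at day 4.

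Interferon response genes, lysosomal genes and receptor tyrosine kinases were higher at day 4. The 13 tested interferon response genes rose by 0.66 on the log2 scale relative to all genes (camera adjusted p = 2.3e-06, and adjusted p = 0.244 with an estimated correlation), all at low levels, with Bst2 at 9.50 ± 4.84 and 8.39 ± 2.11 FPKM (n = 3) and Stat1 at 5.31 ± 1.16 and 5.38 ± 2.69. The 26 lysosome and autophagy genes rose by 0.33 (camera adjusted p = 0.000233, and adjusted p = 0.585 with an estimated correlation), with 0.18 and an adjusted p of 0.0521 without day 4 replicate A. Sqstm1, an autophagy receptor, measured 304 ± 47.4 and 263 ± 49.8 FPKM and Lamp1, a lysosomal membrane protein, 263 ± 45.1 and 264 ± 85.3. Receptor tyrosine kinases rose by 0.38 (camera adjusted p = 0.00594, and adjusted p = 0.244 with an estimated correlation), with 0.28 and an adjusted p of 0.0521 without day 4 replicate A. Of its 11 tested members, Fgfr3 rose from 1.11 ± 1.07 to 4.55 ± 1.05 FPKM (limma, adjusted over the list alone, adjusted p = 0.0439), a call that it lost after median-of-ratios scaling and without day 4 replicate A. Axl and Epha2, the members with the highest FPKM, measured 132 ± 20.7 and 86.2 ± 4.25 at day 0 and 149 ± 21.3 and 82.4 ± 39.8 at day 4. Genes of the stress and amino acid response fell by 0.63 (camera adjusted p = 0.0412, and adjusted p = 0.661 with an estimated correlation), with the serine synthesis genes Psat1 at 350 ± 136 and 136 ± 98.8 FPKM and Phgdh at 259 ± 93.1 and 196 ± 131. That call ended without day 0 replicate A (−0.27, adjusted p = 0.248), day 4 replicate A (−0.37, adjusted p = 0.286), day 4 replicate G (−0.74, adjusted p = 0.0620), day 21 replicate G (adjusted p = 0.0633) or day 21 replicate M (adjusted p = 0.0682). Lineage genes did not pass. Gastrointestinal genes differed by −0.70 (camera adjusted p = 0.265), and passed without day 4 replicate A (−1.49, adjusted p = 0.00213), with Lgals4 at 1255 ± 446 and 726 ± 897 FPKM and Cdx2, an intestinal transcription factor, at 65.0 ± 12.7 and 38.7 ± 27.1. Alveolar and airway genes differed by −0.42 (camera adjusted p = 0.959, its direction opposite to that of the mean), with Foxa1 at 38.6 ± 1.05 and 46.7 ± 9.92 and Abca3, a lipid transporter of surfactant-making cells, at 23.6 ± 2.75 and 22.1 ± 2.51.

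Over all genes, limma called 4 genes at day 4, all lower and all encoding small nucleolar RNAs, which guide the modification of ribosomal RNA. Snora41 measured 495, 148 and 323 FPKM in day 0 replicates A, G and M, Snord100 960, 4513 and 4207, Snord16a 1390, 521 and 1563, and Snord49b 1594, 3884 and 3463. All 4 were listed at 0 in each of the 3 day 4 libraries (limma adjusted p between 4.5e-07 and 1.1e-05). These RNAs carry no poly(A) tail and are short, so an FPKM value of theirs in a polyadenylated library is imprecise. Among the 11087 tested genes that are not small RNAs, 0 passed and 824 had an unadjusted p under 0.05. With all genes, 804 had an unadjusted p under 0.05, 190 higher and 614 lower, where chance gives 558. The median log2 difference of all genes was −0.21, and −0.01 after median-of-ratios scaling. This shift came with day 4 replicate A, without which the median was −0.04 and 516 genes were higher and 436 lower at an unadjusted p under 0.05. The count of called genes was 0 without any single day 0 replicate and 4 or 5 without any single later replicate. Without a day 0 library the 4 genes fell below the filter and were not tested. Of the 22 lists with enough tested members, 17 passed camera, 8 higher and 9 lower. Without day 4 replicate A 12 did, among them epithelial and gastrointestinal genes, which had not passed with all libraries. None passed with an estimated correlation (smallest adjusted p = 0.244).

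**Figure D2:**
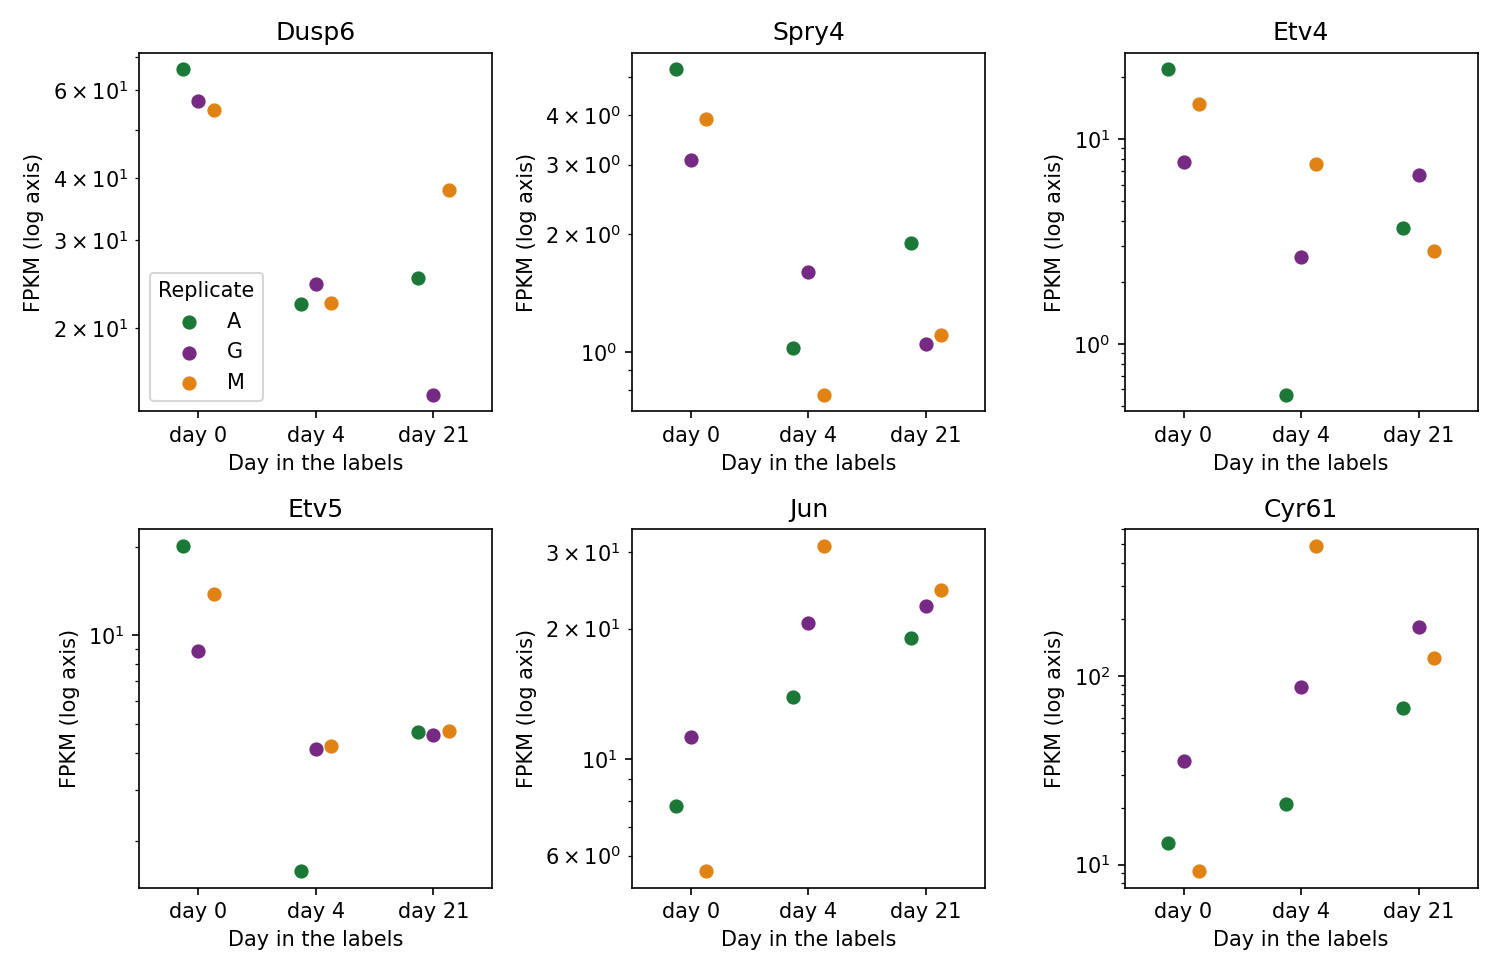
FPKM of Dusp6, Spry4, Etv4, Etv5, Jun and Cyr61 in each of the 9 libraries by day, on a log axis, with points for single libraries. Dusp6 lies between 54.7 and 66.0 FPKM at day 0 and between 14.7 and 37.8 in the 6 later libraries.

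The comparison of day 21 with day 0 asked which of these differences were present late in the series. ERK output genes were divided. All 3 day 21 values lay below all 3 day 0 values in 6 of the 28 and above them in 5, where chance gives 2.8 over both directions. Of the 28, 17 had a negative and 11 a positive log2 difference. Dusp6 measured 59.3 ± 5.96 FPKM (n = 3) at day 0 and 25.9 ± 11.6 at day 21, Spry4 4.08 ± 1.09 and 1.35 ± 0.47, and Etv5 14.3 ± 5.66 and 4.67 ± 0.086. These 3 of 28 tested members fell in limma when adjusted over the list alone (adjusted p = 0.0298 for each). All 3 kept that call after median-of-ratios scaling, but each in only 4 of the 12 settings that left out a library or a letter. Over all genes 0 of the 28 passed, and 6 were lower at an unadjusted p under 0.05. Emp1 and Ccnd1 measured 620 ± 84 and 300 ± 54.0 at day 0 and 514 ± 130 and 313 ± 18.8 at day 21. As a list, ERK output fell by 0.15 on the log2 scale relative to all genes (camera adjusted p = 0.0406, and adjusted p = 0.668 with an estimated correlation), and an adjusted p of 0.0566 after median-of-ratios scaling ended this call. Leaving out any of 6 libraries also ended it, with −0.07 (adjusted p = 0.0641) without day 0 replicate A, −0.14 (0.110) without day 0 replicate G, −0.15 (0.0986 and 0.113) without day 4 replicates A and M, −0.11 (0.0991) without day 21 replicate A and −0.08 (0.349) without day 21 replicate M. It stood at −0.23 without day 0 replicate M and at −0.28 without day 21 replicate G.

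YAP/TAZ target genes were higher at day 21 with less spread than at day 4. Cyr61 measured 19.2 ± 14.2 FPKM (n = 3) at day 0 and 125 ± 57.5 at day 21, Ankrd1, a cardiac ankyrin repeat protein, 18.9 ± 20.8 and 107 ± 29.9, Amotl2 18.9 ± 6.67 and 55.2 ± 14.6, and Ctgf 72.7 ± 11.4 and 204 ± 110. In 9 of the 20 tested members all 3 day 21 values lay above all 3 day 0 values and in 0 below, where chance gives 2 members over both directions. As a list they rose by 0.84 on the log2 scale relative to all genes (camera adjusted p = 1.3e-06, and adjusted p = 0.501 with an estimated correlation), and by 0.67 to 1.02 with any single library or letter left out. No member passed limma over all genes or over the list alone (smallest adjusted p over the list 0.114), and 8 had an unadjusted p under 0.05, all higher. Yap1 measured 27.2 ± 1.23 and 29.3 ± 0.41 FPKM and did not pass, and Myof 224 ± 34.7 and 223 ± 26.0. Hippo components rose by 0.38 (camera adjusted p = 0.0106, and adjusted p = 0.612 with an estimated correlation), a call that ended without day 0 replicate M (0.28, adjusted p = 0.0659) and without day 21 replicate G (0.31, adjusted p = 0.116). Jub measured 25.2 ± 8.92 and 67.3 ± 17.3 FPKM and Wwc1 73.1 ± 0.35 and 111 ± 41.2. AP-1 factors rose by 0.41 (camera adjusted p = 0.0109, and adjusted p = 0.612 with an estimated correlation), with 0.30 and an adjusted p of 0.152 without day 21 replicate M. Jun rose from 8.20 ± 2.90 to 22 ± 2.77 FPKM (limma, adjusted over the list alone, adjusted p = 0.0200), a call kept in 5 of the 12 settings that left out a library or a letter. Jund, Junb and Fos measured 132 ± 73.2, 82.0 ± 30.9 and 0.80 ± 0.59 FPKM at day 21.

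**Figure D3:**
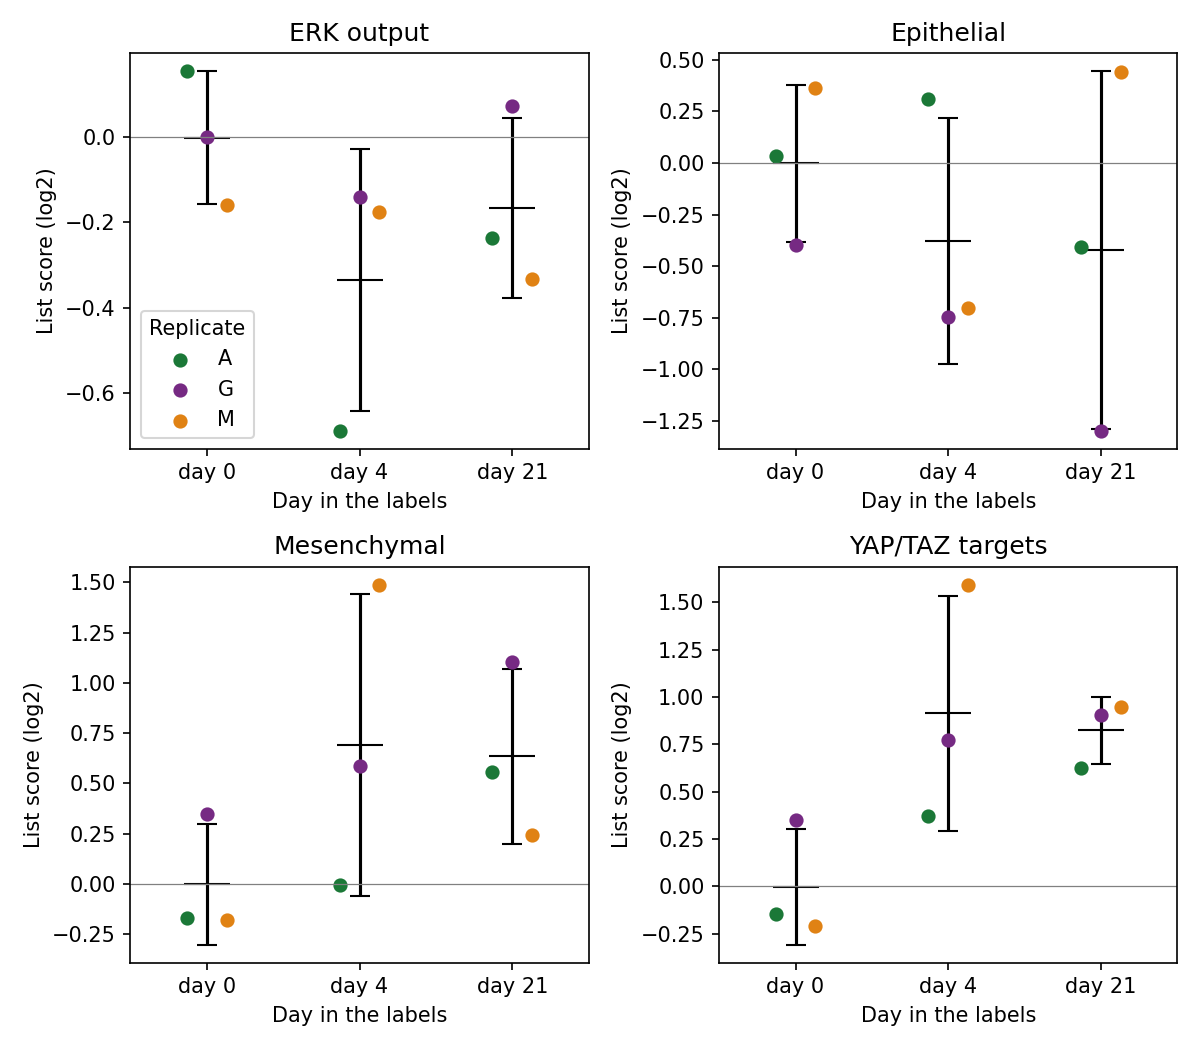
Scores of the ERK output, epithelial, mesenchymal and YAP/TAZ target lists in each of the 9 libraries by day, in log2 units, with the mean of 3 replicates and bars for 1 standard deviation. The YAP/TAZ scores lie between −0.21 and 0.35 at day 0 and between 0.37 and 1.59 in the 6 later libraries.

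Mesenchymal genes were higher and epithelial genes lower at day 21, both resting on replicate G of that day. Fn1, the matrix protein fibronectin, measured 33.8 ± 22.8 FPKM (n = 3) at day 0 and 136 ± 78.9 at day 21, Sparc 125 ± 16.0 and 289 ± 82.9, and Cdh2 4.65 ± 0.78 and 9.15 ± 2.53, while S100a4 measured 3401 ± 1458 and 2516 ± 1024 and Vim 1767 ± 70.0 and 1845 ± 406. As a list, the mesenchymal genes rose by 0.65 on the log2 scale relative to all genes (camera adjusted p = 0.00122, and adjusted p = 0.612 with an estimated correlation), with 0.41 and an adjusted p of 0.210 without day 21 replicate G. The epithelial genes fell by 0.41 (camera adjusted p = 0.0406, and adjusted p = 0.668 with an estimated correlation). They stood at 0.02 (adjusted p = 0.831) without day 21 replicate G and at −0.85 without day 21 replicate M, and the call also ended without day 0 replicate M (−0.23, adjusted p = 0.327), day 4 replicate A (adjusted p = 0.0689) or day 4 replicate M (adjusted p = 0.0531), and after median-of-ratios scaling (adjusted p = 0.0566). Krt8 and Krt19 measured 3136 ± 347 and 1996 ± 631 FPKM at day 0 and 2924 ± 1079 and 2055 ± 1475 at day 21, and Cdh1 177 ± 53.6 and 163 ± 112. No member of either list passed limma over all genes or over the list alone, and 2 mesenchymal and 0 epithelial members had an unadjusted p under 0.05. Col1a1 measured 1.34 ± 1.88 and 5.56 ± 4.31 FPKM, Cd68 1.76 ± 0.52 and 2.01 ± 0.28, Egfl7 3.48 ± 0.17 and 3.37 ± 1.06 and Esam 1.72 ± 0.88 and 0.73 ± 0.11, and none of these markers of other cell types passed.

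Metabolic lists were lower at day 21 by smaller values than at day 4, a difference that the comparison of day 21 with day 4 tests. Glycolysis fell by 0.21 on the log2 scale relative to all genes (camera adjusted p = 0.0109, and adjusted p = 0.612 with an estimated correlation), by 0.11 without day 0 replicate A, and with −0.14 and an adjusted p of 0.134 without day 21 replicate G. Gapdh measured 1500 ± 56.9 FPKM (n = 3) and Pkm2 1090 ± 187 at day 21. NRF2 targets fell by 0.29 (camera adjusted p = 0.0406, and adjusted p = 0.612 with an estimated correlation), with Gsta4 at 585 ± 469 and Gstm1 at 329 ± 265 FPKM. That call ended without day 0 replicate G (−0.34, adjusted p = 0.0646), day 0 replicate M (adjusted p = 0.0607), day 4 replicate A (adjusted p = 0.0636) or day 21 replicate G (−0.10, adjusted p = 0.624), and the list stood at −0.45 without day 21 replicate M. Sterol synthesis fell by 0.23 (camera adjusted p = 0.0406, and adjusted p = 0.668 with an estimated correlation), with Fdps at 197 ± 132 and Srebf2 at 95.1 ± 39.7 FPKM. It stood at −0.07 without day 0 replicate A (adjusted p = 0.416), 0.02 without day 21 replicate G (0.831), −0.19 without day 0 replicate M (0.111) or day 21 replicate A (0.108), −0.23 without day 4 replicates A or M (0.0636 and 0.0531), −0.42 without day 0 replicate G and −0.54 without day 21 replicate M. Ribosomal protein genes fell by 0.16 (camera adjusted p = 1.3e-06, and adjusted p = 0.612 with an estimated correlation), by 0.08 without day 0 replicate A and by 0.27 without day 0 replicate G, but stood at 0.01 under quantile normalisation. Rplp1 measured 2489 ± 436 FPKM and Rplp0 1809 ± 117. Lysosome and autophagy genes rose by 0.16 (camera adjusted p = 0.0392, and adjusted p = 0.668 with an estimated correlation), with Sqstm1 at 313 ± 177 and Lamp1 at 293 ± 155 FPKM. The list stood at 0.14 without day 0 replicate G (adjusted p = 0.0957), 0.16 without day 4 replicate A (0.0689), 0.39 without day 21 replicate G and −0.11 without day 21 replicate M (0.394). Oxidative phosphorylation did not pass (−0.05, camera adjusted p = 0.409), but did without day 21 replicate M (−0.16, adjusted p = 0.0146), with Atp5b at 761 ± 114 and Ndufa4 at 462 ± 140 FPKM.

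Interferon response genes rose by 0.45 on the log2 scale relative to all genes at day 21 (camera adjusted p = 0.000528, and adjusted p = 0.501 with an estimated correlation). The call ended without all libraries of letter A (0.16, adjusted p = 0.112). Bst2 measured 9.02 ± 5.16 and Stat1 6.58 ± 1.49 FPKM (n = 3). Receptor tyrosine kinases rose by 0.24 (camera adjusted p = 0.0415, and adjusted p = 0.501 with an estimated correlation), with Axl at 173 ± 43.4 and Epha2 at 115 ± 22.5 FPKM. That call ended without day 0 replicate A (0.14, adjusted p = 0.150), day 0 replicate M (0.0668), day 4 replicate A (0.0536), day 4 replicate M (0.0531), day 21 replicate G (0.234) or day 21 replicate M (0.0890). With a filter of 5 FPKM the list stood at 0.0236 (adjusted p = 0.586). Gastrointestinal genes fell by 0.73 (camera adjusted p = 0.0189, and adjusted p = 0.612 with an estimated correlation), with Lgals4 at 925 ± 839 and Cdx2 at 37.0 ± 14.7 FPKM, and stood at −0.46 without day 0 replicate M (adjusted p = 0.105), −0.13 without day 21 replicate G (0.359) and −1.24 without day 21 replicate M. Median-of-ratios scaling ended this call too (−0.73, adjusted p = 0.0566). Alveolar and airway genes did not pass (−0.32, camera adjusted p = 0.633), with Foxa1 at 39.3 ± 11.1 and Abca3 at 25.1 ± 13.7 FPKM. DNA replication (−0.01, adjusted p = 0.954), mitosis (−0.22, 0.166), CDK inhibitors (−0.07, 0.182), p53 targets (0.22, 0.151) and the stress response (−0.35, 0.0619) did not pass camera either. The stress response passed without day 0 replicate G (−0.62, 0.00398), day 0 replicate M (−0.44, 0.0256) or day 21 replicate A (−0.37, 0.0485) and stood at 0.02 without day 0 replicate A. DNA replication passed as higher without day 21 replicate M (0.28, adjusted p = 0.0290) and p53 targets passed without day 0 replicate A (0.29, 0.0314). Pcna measured 222 ± 59.7 FPKM, Rrm2 113 ± 52.9, Ube2c 125 ± 44.8 and Top2a 117 ± 56.1. Mitosis passed without day 0 replicate A (−0.30, adjusted p = 0.0314), day 4 replicate A (0.0119) or day 21 replicate G (−0.55, 0.00109), and stood at 0.17 without day 21 replicate M, in which Mki67 was 14.1 FPKM.

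Over all genes, limma called 4 genes at day 21, the same 4 small nucleolar RNA genes as at day 4, all listed at 0 in each day 21 library. Without small RNA genes 0 passed and 375 had an unadjusted p under 0.05. With all genes 376 had an unadjusted p under 0.05, 198 higher and 178 lower, where chance gives 558, and 619 did without day 4 replicate A. The count was 1 without day 0 replicate A, 0 without day 0 replicates G or M, and 4 or 5 without any single later replicate. Without a day 0 library the 4 genes again fell below the filter and were not tested. Of the 22 lists 14 passed camera, 7 higher and 7 lower, and 7 did without day 21 replicate G and 9 without day 4 replicate A. Both of the latter counts include mitosis genes, which had not passed with all libraries. None passed with an estimated correlation (smallest adjusted p = 0.501).

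The comparison of day 21 with day 4 asked whether the later cells differed from the early ones. Genes of several lists had higher means at day 21. Ccnd1, cyclin D1, measured 186 ± 111 FPKM (n = 3) at day 4 and 313 ± 18.8 at day 21, Krt8 1989 ± 444 and 2924 ± 1079, Pkm2 713 ± 198 and 1090 ± 187, and S100a4 1080 ± 279 and 2516 ± 1024. No gene passed limma, 37 had an unadjusted p under 0.05 where chance gives 558, and 32 of the 37 were higher. The median of all genes differed by 0.20, by −0.002 after median-of-ratios scaling and by 0.04 without day 4 replicate A, where 13 genes were higher and 16 lower at an unadjusted p under 0.05. The count was 1 without day 0 replicate A, day 4 replicate A or day 4 replicate M. DNA replication rose by 0.67 on the log2 scale relative to all genes (camera adjusted p = 0.000122, and adjusted p = 0.767 with an estimated correlation). It stood at −0.09 without day 4 replicate A (adjusted p = 0.0866), at 0.38 without day 21 replicate G (0.703), and at 1.08 and 1.01 without day 4 replicates G and M. Mitosis rose by 0.58 (camera adjusted p = 0.00449, and adjusted p = 0.813 with an estimated correlation), stood at −0.18 without day 4 replicate A, where camera called it lower (adjusted p = 0.00379), at 0.24 without day 21 replicate G (0.906), and at 1.08 and 0.99 without day 4 replicate G and day 21 replicate M.

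Glycolysis rose by 0.22 on the log2 scale relative to all genes (camera adjusted p = 0.00281), oxidative phosphorylation by 0.12 (0.000112), sterol synthesis by 0.22 (0.00929), NRF2 targets by 0.23 (0.0170) and ribosomal proteins by 0.10 (7.3e-06). Lysosome and autophagy genes fell by 0.16 (0.00639), although their mean before the median was taken off was 0.03, and interferon response genes by 0.21 (0.0323). Each of these 7 calls was lost at an adjusted p = 0.767 with an estimated correlation. Left out singly, the following libraries ended a call. Glycolysis lost it without day 4 replicate M (0.26, adjusted p = 0.0808) or day 21 replicate M (0.22, 0.0554) and was 0.11 without day 4 replicate A. Oxidative phosphorylation lost it without day 21 replicate M (0.03, adjusted p = 0.281) and was 0.20 without day 21 replicate G. Sterol synthesis lost it without day 4 replicate G (0.20, 0.125), day 4 replicate M (0.18, 0.362) or day 21 replicate M (−0.06, 0.679) and was 0.45 without day 21 replicate G. NRF2 targets lost it without day 4 replicate M (0.11, 0.468), day 21 replicate A (0.15, 0.0869) or day 21 replicate M (0.10, 0.286) and were 0.41 without day 21 replicate G. Ribosomal proteins lost it without day 4 replicate G (0.002, 0.214), were 0.23 without day 4 replicate A, 0.06 without day 4 replicate M and 0.04 without day 21 replicate A, and stood at −0.01 under quantile normalisation and at an adjusted p of 0.114 after median-of-ratios scaling. Lysosome genes lost it without day 4 replicate A (−0.03, 0.623), day 4 replicate M (−0.15, 0.148) or day 21 replicate G (0.05, 0.531) and were −0.30 and −0.41 without day 4 replicate G and day 21 replicate M. Interferon response genes lost it without day 0 replicate M (−0.20, 0.0525), day 4 replicates A or M (−0.10, 0.708 and −0.24, 0.0672), or day 21 replicates G or M (−0.04, 0.917 and −0.24, 0.0554), and were −0.36 without day 4 replicate G. They also lost it after median-of-ratios scaling (−0.17, adjusted p = 0.170).

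The lists central to the series did not pass between day 4 and day 21. ERK output differed by 0.17 on the log2 scale (camera adjusted p = 0.182), and passed without day 4 replicate G (0.27, adjusted p = 0.0475). Epithelial genes differed by −0.04 (0.336), mesenchymal genes by −0.05 (0.579) and YAP/TAZ targets by −0.08 (0.170). Leaving out 1 library gave calls in both directions for epithelial genes, at 0.31 (camera adjusted p = 0.0144) without day 4 replicate A, −0.20 (0.0253) without day 4 replicate M and −0.46 (0.00198) without day 21 replicate M. Mesenchymal genes passed at −0.39 (0.0144) without day 4 replicate A and at −0.25 (0.0299) without day 21 replicate G, but stood at 0.34 (0.222) and 0.23 (0.0616) without day 4 and day 21 replicates M. YAP/TAZ targets passed at −0.35 (0.00379) without day 4 replicate A and stood at 0.25 (0.468) without day 4 replicate M. The other lists did not pass either, with 0.01 (0.579) for the RAS pathway genes, −0.03 (0.701) for Hippo components, 0.04 (0.579) for AP-1 factors, −0.16 (0.152) for CDK inhibitors, −0.05 (0.274) for p53 targets, 0.11 (0.464) for alveolar and airway genes, −0.02 (0.152) for gastrointestinal genes, −0.13 (0.152) for receptor tyrosine kinases and 0.30 (0.464) for the stress response. Of these, gastrointestinal genes passed in opposite directions without day 4 replicate A (0.75, adjusted p = 0.0144) and without day 4 replicate M (−0.68, 0.00107), and at −0.14 (0.0490) without day 21 replicate A. Hippo components passed without day 4 replicate A (−0.16, 0.0140) and CDK inhibitors without day 21 replicate A (−0.21, 0.0490). For AP-1 factors and alveolar and airway genes the direction of the camera test was opposite to that of the mean. Yap1 measured 26.9 ± 10.4 FPKM (n = 3) at day 4 and 29.3 ± 0.41 at day 21, a log2 difference of 0.19 that was −0.03 after median-of-ratios scaling, and Vim 1503 ± 458 and 1845 ± 406. Of the 22 lists 9 passed camera, 7 higher and 2 lower.

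The comparisons of days 4 and 21 with day 0 share the same 3 day 0 libraries, so their agreement was set against simulated unchanged groups. Across the 11168 genes, which are not independent replicates, the log2 differences of the 2 comparisons had a Pearson r of 0.79. In 100 simulations, pairs of unchanged groups that shared a simulated day 0 group gave 0.50. The simulations drew every gene and library independently, day 0 included. They lack shifts that many genes share within a library, so they cannot decide whether the agreement goes beyond the shared day 0 libraries. Their covariance was 0.238 against 0.13 in the simulations. Both comparisons called the same 4 genes, all small nucleolar RNAs, where independent lists would share 0.00143. That expectation leaves out the shared day 0 libraries, so it is too low for these comparisons. Without small RNA genes r was 0.84 against 0.50, and 0 genes were called in either comparison. The sign was shared by 69.8% of the genes, against 66.7% in the simulations.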

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

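The counts over other splits of the libraries were set before their results were seen, although taking days 4 and 21 together was chosen after the counts of each day were seen, and the tests on day 4 replicate A were chosen after as well.

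The comparison of day 21 with day 4 singled out 9 gene lists whose differences from day 0 at the 2 times differed in the camera test, and no such call held with an estimated correlation (adjusted p from 0.767 to 0.813). The mean log2 difference of day 21 from day 4, less the median of all genes, was 0.667 for DNA replication and 0.577 for mitosis. It was 0.222 for glycolysis, 0.122 for oxidative phosphorylation, 0.222 for sterol synthesis, 0.227 for NRF2 targets and 0.0960 for ribosomal proteins. It was −0.164 for lysosome and autophagy genes and −0.207 for interferon response genes. The libraries that decide each of these values are named in the report.

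Cell cycle genes were low in day 4 replicate A, which decides both cell cycle values above. Lower sequencing depth is argued against, since the spacing of its lowest FPKM values gave a relative depth of 1.26 with day 0 replicate A at 1 and the other 7 libraries between 0.461 and 0.779. Its mitosis score was −2.35 before and −2.36 after median-of-ratios scaling, against −1.06 for the next lowest library. The score already takes off the shift of the median gene, so scaling could hardly move it and is no separate test of the scale of the FPKM values. The score shows only that mitosis genes were low relative to the other genes of that library. A day 0 library under a wrong label is argued against by its Kras value of 2.14 FPKM, below the day 0 range of 7.98 to 25.6. Lower Kras by itself is not settled. The other 5 later libraries had Kras of 1.93 to 3.32 FPKM and a median scaled mitosis score of −0.0323, within the day 0 range of −0.149 to 0.154. Yet day 21 replicate M, with the lowest Kras (1.93 FPKM), stood at −1.06, and day 4 replicate M (3.32 FPKM) at −0.281, both below that range. Day 4 replicate G and day 21 replicates A and G stood at 0.201, −0.0323 and 0.382. Slower growth of this culture at harvest, with or without a part for Kras, could account for it and was not tested. A swap with a day 21 library was not tested either. It would only move the low score to day 21, where the libraries stood between −1.06 and 0.382.

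Other splits of the libraries were counted for each comparison. For 3 against 3 libraries, the 10 splits cannot give a share under 0.05. The real split of day 4 and day 0 gave 4 called genes, the highest other split 5, and 2 splits gave as many as the real one. For day 21 and day 0 these were 4, 9 and 2 splits, and for day 21 and day 4 they were 0, 2 and 10 splits. For the lists called by camera the real and highest other counts were 17 and 15 for day 4 and day 0, with 1 split as large, 14 and 11 for day 21 and day 0, with 1 split as large, and 9 and 12 for day 21 and day 4, with 2 splits as large. With days 4 and 21 as 1 group, 4 of the 84 splits of 6 against 3 called at least as many genes as the real split, which called 5, a share under 0.05. Of these 5 genes, 4 were the small nucleolar RNA genes already called at each day, so the share is not separate evidence. The highest of the other splits called 167 genes and set day 0 replicates A and M and day 21 replicate M apart from the rest, which points to a structure of the samples other than day.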

How the results depend on the processing

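Alternatives chosen only after the data were seen were the fits without small RNA genes, with and without median-of-ratios scaling, the library weights and the tests of days 4 and 21 together; all others were planned. Keeping several lines per symbol was not run, since no symbol is repeated.

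The Kras difference from day 0 passed in 25 of 25 settings at both times, from −2.41 to −1.33 at day 4 (largest limma adjusted p 0.00309) and from −2.49 to −1.35 at day 21 (largest limma adjusted p 0.00495), each adjusted over this 1 gene alone, which leaves p as it is. YAP/TAZ targets kept their camera call against day 0 in every setting but the estimated correlation, with 0.48 to 1.20 at day 4 and 0.67 to 1.02 at day 21 as libraries were left out. Robust moderation changed no count of calls. For the values that follow, the cause was not tested unless it is named.

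As deposited, 4, 4 and 0 genes were called at day 4 against day 0, day 21 against day 0 and day 21 against day 4, with 4 shared by the first 2 sets, and 17, 14 and 9 lists. With no expression filter, 8 genes were called at day 4 against day 0, RAS pathway genes (−0.12) and CDK inhibitors (−0.0671) turned sign and mesenchymal genes (0.33) lost the call. Epithelial genes (−0.27) lost the call at day 21 against day 0, where 7 lists were called. Against day 4 in the same setting, ERK output (0.33) gained a call. Epithelial genes (0.0903), mesenchymal genes (0.0885), YAP/TAZ targets (0.0661), Hippo components (0.13), CDK inhibitors (0.0135), p53 targets (0.12), gastrointestinal genes (0.0707), lysosome and autophagy genes (0.00789) and receptor tyrosine kinases (0.0151) turned sign there. With FPKM of at least 5 in 3 libraries, ERK output (−0.15) and epithelial genes (−0.41) lost the call at day 21 against day 0, where 9 lists were called, and RAS pathway genes (−0.0213) and epithelial genes (0.0531) turned sign at day 21 against day 4. Pseudocounts turned the sign of RAS pathway genes (−0.000155) and mesenchymal genes (0.0817) with 0.1, and of epithelial genes (0.0428) and gastrointestinal genes (0.00369) with 5, all at day 21 against day 4.

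Without small RNA genes, 0 genes were called at day 4 and 0 at day 21 against day 0, with 0 shared, as the called genes were those left out. Without small RNA genes and with median-of-ratios scaling, 0 and 0 genes were called and 0 shared, Yap1 turned sign at day 4 against day 0 (0.13) and, with Cdh1, at day 21 against day 4 (−0.0262 and −0.18), where ERK output (0.18) gained a call. With median-of-ratios scaling alone, Yap1 turned sign at day 4 against day 0 (0.13) and, with Cdh1, at day 21 against day 4 (−0.0262 and −0.18). ERK output (−0.15) and epithelial genes (−0.40) lost the call at day 21 against day 0. With quantile normalisation, Yap1 (0.14), Vim (0.28) and ribosomal proteins (0.0314) turned sign at day 4 against day 0. At day 21 against day 0 it called 7 lists, ERK output (−0.14) and epithelial genes (−0.40) lost the call, and DNA replication (0.000661) and ribosomal proteins (0.0130) turned sign. At day 21 against day 4 it turned the sign of Yap1 (−0.0402), Cdh1 (−0.24), RAS pathway genes (−0.0106) and ribosomal proteins (−0.0135).

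In fits of only the 2 groups compared, epithelial genes (−0.36) gained a call at day 4 against day 0. At day 21 against day 0 ERK output (−0.15) and epithelial genes (−0.41) lost it and 9 lists were called. At day 21 against day 4, 1 gene was called. With library weights, estimated gene by gene from 0.132 (day 4 replicate A) to 8.86 (day 21 replicate A), 6, 266 and 1 genes were called. The default estimate was tried first and did not converge (weights from 0.0781 for day 4 replicate A to 45.1 for day 4 replicate G, with 4210, 1947 and 7202 calls), so it was not used. Under the weights at day 4 against day 0, ERK output (−0.11) lost the call, epithelial genes (−0.83) gained a call, and mitosis (0.0485) and CDK inhibitors (−0.0666) turned sign. For day 21 and day 0 they called 9 lists, Vim (−0.0807), DNA replication (0.0196) and CDK inhibitors (0.0144) turned sign and ERK output (−0.17) lost the call. For day 21 and day 4 they called 3 lists. Kras (0.14), ERK output (−0.0597), RAS pathway genes (−0.0719), epithelial genes (0.28), AP-1 factors (−0.0309), mitosis (−0.0950), CDK inhibitors (0.0796), p53 targets (0.0833), gastrointestinal genes (0.47), lysosome and autophagy genes (0.0370) and interferon response genes (0.16) turned sign there.

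With an estimated correlation, limma's camera called 0, 0 and 0 lists. Adjusted p from limma was 0.622 for ERK output, 0.549 for mesenchymal genes and 0.381 for YAP/TAZ targets at day 4 against day 0. At day 21 against day 0 adjusted p from limma was 0.668 for ERK output, 0.668 for epithelial genes, 0.612 for mesenchymal genes and 0.501 for YAP/TAZ targets.

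The replicate letters were tried as a block, although the labels do not say that a letter marks a shared origin. Deviations of libraries with the same letter correlated at −0.06 to 0.46, with 6 of 9 pairs above 0.1. Those of libraries with different letters and days correlated at −0.45 to 0.30. Of the 9 libraries, 5 correlated best with a library of their own letter among those of other days. A shared origin of the libraries of a letter therefore stays open, and the main fit, planned without a block, does not allow for it. With the replicate block, 4, 4 and 0 genes and 16, 12 and 8 lists were called, and 4 list calls ended, with no other list call changed. These were ERK output (−0.15, camera adjusted p = 0.0779) and NRF2 targets (adjusted p = 0.0610) at day 21 against day 0, NRF2 targets at day 21 against day 4 (0.0534) and the stress response at day 4 against day 0 (0.0926) under the block. With the replicate block and median-of-ratios scaling, Yap1 turned sign at day 4 against day 0 (0.13) and, with Cdh1, at day 21 against day 4 (−0.0262 and −0.18). In the same setting with the block, epithelial genes at day 4 against day 0 (−0.36) and ERK output at day 21 against day 4 (0.18) passed, and ERK output at day 21 against day 0 (−0.15) did not.

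Leaving out 1 library leaves its day with 2, and leaving out a letter leaves 2 per day. Over these 12 settings, 0 to 5 genes were called at day 4 against day 0, 0 to 5 at day 21 against day 0 and 0 to 2 at day 21 against day 4, with 0 to 5 shared, and 7 to 14 lists at day 21 against day 0 and 5 to 11 at day 21 against day 4. The 4 small nucleolar RNA genes fell below the filter in each setting that left out a day 0 library, so the low gene counts against day 0 follow from the filter. Values at day 4 against day 0 ran from −0.36 to 0.23 for Yap1, −0.48 to −0.0793 for ERK output, −0.0107 to 0.13 for RAS pathway genes and −0.73 to −0.0819 for epithelial genes. They were 0.26 to 1.07 for mesenchymal genes, −1.08 to 0.0733 for DNA replication, −0.0440 to 0.22 for CDK inhibitors and −1.49 to 0.21 for gastrointestinal genes. Values at day 21 against day 0 ran from −0.82 to 0.19 for Cdh1, −0.13 to 0.14 for Vim, −0.28 to −0.0347 for ERK output, −0.85 to 0.0161 for epithelial genes, 0.41 to 0.92 for mesenchymal genes and −0.28 to 0.36 for DNA replication. Mitosis gave −0.55 to 0.17, CDK inhibitors −0.25 to 0.10, alveolar and airway genes −0.84 to 0.19 and oxidative phosphorylation −0.16 to 0.0461. Lysosome and autophagy genes gave −0.11 to 0.39, sterol synthesis −0.54 to 0.0185 and stress and amino acid response −0.65 to 0.0204. Values at day 21 against day 4 ran from −0.21 to 0.22 for Kras, −0.10 to 0.46 for Yap1, −0.0642 to 0.42 for Fos and −0.48 to 0.53 for Cdh1. ERK output gave 0.00313 to 0.34, RAS pathway genes −0.0519 to 0.0571, epithelial genes −0.57 to 0.37 and mesenchymal genes −0.39 to 0.62. YAP/TAZ targets gave −0.35 to 0.25, Hippo components −0.16 to 0.16, AP-1 factors −0.0748 to 0.18, DNA replication −0.13 to 1.33 and mitosis −0.28 to 1.26. CDK inhibitors gave −0.31 to 0.000539, alveolar and airway genes −0.36 to 0.41, gastrointestinal genes −1.16 to 0.75 and lysosome and autophagy genes −0.41 to 0.0547. Sterol synthesis gave −0.11 to 0.45, NRF2 targets −0.0201 to 0.51 and stress and amino acid response −0.00295 to 0.54.

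Other list calls ended as follows. With no expression filter these were Hippo components (0.22) and p53 targets (0.0772) at day 4 against day 0, interferon response (−0.0189) at day 21 against day 4, and 6 lists at day 21 against day 0. The 6 were gastrointestinal genes (−0.37), glycolysis (−0.19), lysosome and autophagy (0.15), sterol synthesis (−0.22), receptor tyrosine kinases (0.16) and NRF2 targets (−0.30). With FPKM of at least 5 they were receptor tyrosine kinases (0.17) and the stress response (−0.59) at day 4 and receptor tyrosine kinases (0.0236) and NRF2 targets (−0.29) at day 21, both against day 0. Median-of-ratios scaling ended p53 targets at day 4 (0.27) and gastrointestinal genes at day 21 (−0.73) against day 0, and interferon response (−0.17) and ribosomal proteins (0.0683) at day 21 against day 4. Without small RNA genes the same scaling ended 3 of these (p53 0.27, interferon −0.17, ribosomal 0.0684), and with the replicate block gastrointestinal genes (−0.73), interferon response (−0.17), ribosomal proteins (0.0683) and NRF2 targets at day 21 against day 0 (−0.29). Quantile normalisation ended p53 targets (0.26) and oxidative phosphorylation (−0.0492) at day 4, and gastrointestinal genes (−0.71), glycolysis (−0.12), lysosome and autophagy (0.15) and receptor tyrosine kinases (0.21) at day 21. Between the later days it ended oxidative phosphorylation (0.0221) and interferon response (−0.13). Fits of 2 groups ended the stress response (−0.63) at day 4, lysosome and autophagy (0.16), sterol synthesis (−0.23), receptor tyrosine kinases (0.24) and NRF2 targets (−0.29) at day 21, and interferon response (−0.21) between the later days. Library weights ended DNA replication (−0.00203), p53 targets (0.21), lysosome and autophagy (0.0639) and the stress response (−0.42) at day 4. At day 21 they ended AP-1 factors (0.37), glycolysis (−0.0959), lysosome and autophagy (0.10), receptor tyrosine kinases (0.20) and NRF2 targets (−0.20). Between the later days they ended DNA replication (0.0202), sterol synthesis (0.20) and NRF2 targets (0.21).

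Of the calls at day 4 against day 0, YAP/TAZ targets, glycolysis, oxidative phosphorylation, sterol synthesis, interferon response, NRF2 targets and ribosomal proteins held in 12 of the 12 settings that leave out a library or a letter. Mesenchymal genes and AP-1 factors held in 11, Hippo components, mitosis, lysosome genes and receptor tyrosine kinases in 10, ERK output and DNA replication in 9, p53 targets in 7 and the stress response in 6. At day 21 against day 0 YAP/TAZ targets and ribosomal proteins held in 12, and mesenchymal and interferon response genes in 11. Hippo components, AP-1 factors and glycolysis held in 10, gastrointestinal genes in 9, and epithelial genes, lysosome genes and NRF2 targets in 7. ERK output and sterol synthesis held in 4 and receptor tyrosine kinases in 3. Between the later days oxidative phosphorylation and ribosomal proteins held in 10, DNA replication and mitosis in 9, glycolysis, sterol synthesis and NRF2 targets in 8, lysosome genes in 7 and interferon response genes in 4.

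Of 1401 values of the 54 list results outside the central lists under all settings, 1130 kept direction and side of the threshold, 169 lost the call, 26 gained it and 76 turned sign. For the 12 results of the central lists these numbers were 237, 38, 18 and 19. Of 472 values of 19 members past the threshold over their list alone, 245 kept the call and 227 lost it, with 0 turned. Fragment counts are not in the table, so the counts that limit low values cannot be computed; genes with no value in a setting, such as those outside its filter, have none given.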

Other observations

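All tests of this part were chosen after the results were seen.

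Some lineage genes differed widely between libraries of the same day. Nkx2-1, the transcription factor of lung epithelium, measured 28, 0.011 and 25.4 FPKM in day 0 replicates A, G and M, 0.108, 0.055 and 19.7 at day 4 and 0.064, 0.078 and 44.3 at day 21. Hnf4a, a transcription factor of liver and gut, measured 65.0, 46.5 and 75.3 FPKM at day 0, 50.5, 40.4 and 16.0 at day 4 and 51.0, 11.9 and 58.8 at day 21. Sdc3, a cell surface proteoglycan, measured 0.139, 12.0 and 0.529 FPKM at day 0, 1.88, 13.9 and 2.77 at day 4 and 8.06, 26.3 and 1.27 at day 21. The first 3 principal components of the log2 values held 28.2%, 23.3% and 19.1% of the variance.

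In a fit of 2 groups, the 6 later libraries against day 0, limma called 5 genes. Beside the 4 small nucleolar RNA genes this was Gm5779, a predicted gene, which measured 22.2, 15.3 and 19.7 FPKM at day 0 and 5.53 to 7.77 FPKM in the 6 later libraries (log2 difference −1.30, limma adjusted p = 0.0336). The 3-group fit used in the report called only the 4 small nucleolar RNA genes when days 4 and 21 were set against day 0, with 0.0763 as the smallest limma adjusted p of any other gene, and in that fit without small RNA genes Gm5779 had an adjusted p of 0.349.

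Sets of genes were on (at least 10 FPKM) in some libraries and off (under 0.5 FPKM) in others of the same day. Letters that stand for lines of cells could underlie this and stay open. The median count of genes on in 1 library and off in the other was 12 for pairs of the same letter and 23 for pairs of different letters, and Nkx2-1 was off in all 3 libraries G and on in all 3 libraries M. Yet the count reached 47 within a letter and fell to 1 between letters, and without day 0 replicate A, in case its letter alone is wrong, the former still exceeded the latter by 46. Mixed populations of cells in changing shares stay open too. Nkx2-1 lay between the on and off limits in 0 libraries, but the limits alone cannot exclude a mixture. Sdc3 did take values between the limits, such as 1.88 FPKM in day 4 replicate A and 8.06 FPKM in day 21 replicate A. No biological explanation was tested.

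The 4 small nucleolar RNA genes were above 0 in the 3 day 0 libraries and listed at 0 in the 6 others. Loss of the host genes is argued against, since the median log2 difference of the hosts Eef1b2, Rps12, Rpl4 and 2410006H16Rik over both days was −0.416, with Rps12 still at 1781 ± 53.8 FPKM at day 4. Switching of very short genes from library to library without regard to day could underlie it and stays open. Of 25 small RNA genes above 0 in exactly 3 libraries, 4 had the day 0 set where 0.640 would be given detection in each library (exact binomial p = 0.00353), but these 4 prompted the count, so it excludes nothing. A higher content of small RNA at day 0 than at day 21 is argued against, since the lowest day 0 share of the FPKM sum minus the highest day 21 share was −11.1 percentage points (SD over day 0 6.03), and the 4 genes were at 0 in day 21 replicates A and G with shares of 22.8% and 28.1%. For day 4 the same difference was 1.32 percentage points, which leaves a higher content at day 0 open. The number of small RNA genes above 0, these 4 included, was 84, 73 and 60 in day 0 replicates A, G and M. It was 54, 47 and 46 at day 4, below each day 0 library, and 60, 65 and 41 at day 21, where the ranges overlapped. Estimated depth differed between libraries, so these numbers do not settle the question either.

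YAP/TAZ target scores lay above all 3 day 0 scores in 6 of 6 later libraries. The hypothesis that these genes are higher once Kras is lowered was tested over the 84 splits of 6 against 3 libraries. The splits set day 0 against the later days, so they cannot tell lower Kras from doxycycline or time. The score was 0.87 higher in the later libraries (exact permutation p = 0.0119, the smallest possible), and the exact p adjusted over the 22 lists was 0.150, so it did not pass. With that smallest p, no list could pass the adjustment unless several others came with a p as small. ERK output scores lay below all day 0 scores in 4 of 6 later libraries, with a difference of −0.25 and an adjusted exact permutation p of 0.349. Both hypotheses stay open at this number of libraries.

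Within ERK output, the 12 tested genes of the Dusp, Spry, Spred and Etv families had a mean log2 difference from day 0, averaged over days 4 and 21, of −0.66 (SD 0.65), and the other 16 members −0.11 (SD 0.64). A permutation of the genes gave p = 0.0343. The families were set apart after their values were seen and genes of a list are not independent, so a larger fall of these families is a hypothesis that these data leave open.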
